A study of Mus musculus with 4 samples.

How the data were processed

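Single-cell 3′ gene expression and hashtag antibody tags were measured in 2 sorted populations of mouse CD4 T cells, 1 lane of the 10x Genomics system each. Per the labels, the Tfh sort used version 2 chemistry and a HiSeq 4000, and the IL-4 reporter sort used version 3 chemistry and a NovaSeq. Per the labels, cells of each mouse of a sort were stained with their own hashtag before pooling. The deposited gene matrices hold raw UMI counts per gene and cell barcode, and the deposited hashtag tables hold raw tag counts per hashtag and barcode, with no statement whether molecules or reads were counted. The submitters' processing notes name Cell Ranger 2.2.0 and bcl2fastq 2.18.0.12 and 2.20.0.422 for all samples, with builds mm10 and GRCm38. Per the file headers, the reporter matrix came from Cell Ranger version 3.0.2, so these sources differ. Neither source gives the annotation release. Both matrices list 28692 features, and the counts of features with the same symbol (67 duplicates) were summed.

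Cells needed 500 or more genes and at most 10% mitochondrial UMIs (13 genes). In the Tfh sort 3916 of 3956 barcodes passed (99.0%). In the IL-4 reporter sort 4585 of 7646 passed (60.0%), with 2772 above the mitochondrial limit and 1201 under 500 genes. HTODemux of Seurat 5.3.0 (quantile 0.99, seeded) assigned cells to mice from the 3 hashtags that held counts, where the labels mention 1 more. The Tfh sort gave 3703 singlets, 190 doublets (4.85%) and 23 negatives (0.587%), and the reporter sort 3866, 165 (3.60%) and 554 (12.1%). Doublets within a mouse cannot be seen by hashtags, and the rates between mice put them near 2.43% and 1.80%. Cell numbers per mouse were 1401, 1405 and 897 in the Tfh sort and 1345, 1147 and 1374 in the reporter sort.

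Cells were clustered per sort with scanpy 1.11.5, scikit-learn 1.9.0 and igraph 0.11.9 under Python 3.11.15, after scaling to 10000 counts per cell. The clustering used 2000 variable genes seen in 10 or more cells, 30 principal components, 20 neighbours with a Jaccard index of 0.0667 or more, and Leiden at resolution 1 (0.5 and 1.5 as alternatives). It left out 35 cytokine, regulator and helper genes that later comparisons test, with mitochondrial, ribosomal and T-cell receptor genes. Clusters were named by marker lists, and clusters named for cells other than CD4 T cells were kept out of the states, but an unnamed reporter-sort cluster with macrophage transcripts stayed in. The graph step was rewritten after first results were seen, only so that a rerun gives the same clusters, and an error in how library sizes entered the fit was mended at the same stage.

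UMIs were summed per mouse and state, each sum needing 10 or more cells. edgeR 4.0.16 in R 4.3.3 fitted quasi-likelihood models with TMM factors, filterByExpr at a minimum count of 10 and Benjamini-Hochberg adjustment at 0.05. All 3 states of a sort shared 1 fit (9 sums, 4 residual degrees of freedom), and the class comparisons had 6 sums and 2 residual degrees of freedom. Each mouse gives every state, so the mouse entered as a block. Fixed gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01 and with an estimated one, and with fry. At matched depth camera used the preset correlation only. DESeq2 1.42.0 served as another tool. On simulated counts with 100 genes changed 4-fold, edgeR recovered 68% for Il13+ against Il4+ Il13− cells of the Tfh sort, 93% for Il4+ Il13− against Il4− Il13− cells, 84% for the reporter sort and 91% for its Tfh-like cells. For 2-fold changes it recovered 37%, 76%, 60% and 68%.

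Genes named in the text follow a rule. Il4, Il5, Il13, Il21, Ifng, Gata3, Bcl6, Cxcr5, Pdcd1 and Foxp3 were named in each comparison that measured them. So were the 10 largest rises and falls at an adjusted p under 0.05 with the same direction in 3 of 3 mice and 20 CPM or more in the higher state, and up to 4 passing members of each fixed list. Gene models without a proper name were passed over, and a few genes that the rule names are not reported here. Genes set beside these in descriptions of the Il13+ cells of the Tfh sort, of low counts and of the closing section were chosen after their values were seen. The states, contrasts, gene lists, naming rule and most alternatives were fixed before the data were examined. Alternatives changed the tool, size factors, low-count filter, block, fitted states, UMI limit, cell filter, hashtag rule (10 counts and a ratio of 3), clustering resolution or class definition, matched the 2 compared states for depth within each mouse in 5 bins, or left out a mouse or cells with a Foxp3 UMI. Size factors from RLE in place of TMM moved the median log2 change of the tested genes by less than 0.1 in each comparison.

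Folds against 0 counts use a floor of 3 counts over the group, ratios on 1 to 3 counts carry a 95% counting interval, and upper limits for shares of 0 use 3 counts. Intervals and floors cover counting error only. Coordinates are GRCm38 with GENCODE M21. scipy 1.17.1, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were also used.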

Results

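Droplet 3′ RNA counts were collected from 2 populations of activated CD4 T cells, taken from the mediastinal lymph node 7 days after intranasal Alternaria extract with the hapten-carrier antigen NP-OVA. The Tfh sort kept cells with surface PD-1 and CXCR5 from 3 C57BL/6 mice. The IL-4 reporter sort kept GFP-positive cells from 3 mice of the 4get strain, in which a GFP cassette follows the Il4 coding sequence. Cells of both sorts were stimulated with PMA and ionomycin for 30 minutes, so cytokine transcripts reflect restimulation. Each mouse carried its own hashtag antibody, and the mouse is the replicate throughout (n = 3 per sort). Values are CPM (UMI counts scaled to a total) as mean ± SD over 3 mice, and fold changes are log2. CPM in the edgeR comparisons use the TMM-scaled total of each sum. CPM in descriptions by cluster, of B-like cells and of all CD4 cells use plain totals, so the same cells can differ slightly between them.

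The Tfh sort held 3703 cells assigned to a mouse, with 5165093, 5197774 and 3351729 UMIs in the 3 mice and medians of 2748, 2606 and 2721 UMIs per cell. The IL-4 reporter sort held 3866 such cells, with 12254650, 11844384 and 14529446 UMIs and medians of 6733, 6631 and 6605.5. Each sort was a single 10x lane, and strain, 10x chemistry and sequencing run differ together with the sort, so no test was made between sorts. Clusters used as CD4 T cells numbered 2995 and 3567 cells. The latter include a reporter-sort cluster of 143 cells led by macrophage genes (Lyz2, C1qa, C1qb), 8 of them Il13+, that was kept. Cells were put in 3 states. Il13+ cells had 2 or more Il13 UMIs, Il4+ Il13− cells had 2 or more Il4 UMIs and none of Il13, and Il4− Il13− cells had none of both. The labels name no cytokine beyond IL-4. The focus on Il13, whose protein with IL-4 drives type 2 immunity, came from knowledge of the field. Il4 and Il13 define the states and are not results where states are compared.

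The first comparison asked which genes separate IL-13-transcribing cells from other IL-4-transcribing cells of the Tfh sort. Among the largest rises in Il13+ cells were those of Il5, Il3 and Csf2. Il5, the eosinophil cytokine gene, which lies near Il13 on chromosome 11 (GRCm38, GENCODE M21, 53720794 to 53725106), reached 318 ± 24.7 CPM against 1.07 ± 1.41 (8.31 ± 0.37 SE, edgeR adjusted p = 1.1e-31, higher in 3 of 3 mice). Few cells carried it, since an Il5 UMI was in 11.5, 9.68 and 9.09% of the Il13+ cells of the 3 mice (68 cells in all). Il3, a growth factor gene for mast cells and basophils, reached 1212 ± 831 CPM against 4.75 ± 1.07 (edgeR adjusted p = 1.7e-51, a log2 rise of 8.05, 3 of 3 mice). Csf2, which encodes the growth factor GM-CSF, stood at 131 ± 135 CPM against 0 counts, at least 219-fold higher over a floor of 3 counts for the group. Ccl1, a chemokine gene whose product binds CCR8, rose from 74.9 ± 30.4 to 5300 ± 2487 CPM, a log2 change of 6.23. Gata3, the type 2 lineage regulator, rose by 1.35 to 325 ± 76.9 CPM (edgeR adjusted p = 1.3e-10, 3 of 3 mice).

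Other large rises were in Ltb4r1 (7.12), a leukotriene B4 receptor gene, Plac8 (6.24), a gene of effector lymphocytes, Il6 (5.86), Ccr2 (4.62), a receptor gene for inflammatory chemokines, and Cxcl3 (4.59). Ggt1, a glutathione-handling enzyme gene, was 79.9 times higher with a counting interval of 24.1 to 416. Ifng, the type 1 cytokine gene, also rose, from 48.2 to 298 ± 164 CPM (2.61). Its UMIs lay in few Il13+ cells (5 of 29 in an effector-like cluster and 3 of 39 in other clusters). Without that cluster Ifng stood at 0.06 and did not pass, but mouse 3 gave no Il13+ sum in that fit. An Ifng UMI was in 27.3% of the Il13+ cells of mouse 3, against 7.69% and 9.68% in mice 1 and 2. Pdcd1, which encodes PD-1, rose by 0.81. The largest falls were in Ctnnbip1, an inhibitor of β-catenin signalling, which was 11.7 times lower (interval 2.06 to 466), Dennd2d (−2.40), Tspan5 (−2.34), the interferon receptor gene Ifnar2 (−2.00), Tubb2a (−1.84, uncertain because tubulin paralogs share reads), Fam122a (−1.82), the splicing regulator Mbnl2 (−1.69), Actn1 (−1.60), Il16 (−1.59) and the transcript-end processing gene Pcf11 (−1.58). Il21, whose product helps B cells, stood at −0.16, the Tfh regulator Bcl6 at −0.06 and Cxcr5 at −0.51 (62.7 against 101 CPM), and none of them passed.

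Of 16 type 2 genes measured, 13 rose, 0 fell and 3 did not pass (14 rose adjusted over the list alone). Of 16 genes of non-Tfh effector cells, 12 rose and 4 did not pass (13 adjusted over the list alone), among them Lgals1 (3051 against 1019 CPM, 1.57), Vim (2.42), Crip1 and S100a6 (1.54), which mark tissue-homing effector cells. Of 22 Tfh genes, Pdcd1 rose, 6 fell and 15 did not pass (2 rose and 9 fell adjusted over the list alone), with falls in Tcf7 (−0.84), Tox2 (−1.30) and Cd200 (−0.87). Of 9 Th1 genes, 4 rose and 5 did not pass (6 adjusted over the list alone), including Cxcr6 (3.59), Nkg7 (3.21), Id2 (1.02) and Ifng. Of 9 Treg genes 3 rose (5 rose and 1 fell adjusted over the list alone), including Il2ra (2.57), Il10 (1.12, in 2 of 3 mice) and Capg (1.66). Of 4 Th17 genes 2 rose, Ltb4r1 and Rora (0.90), and of 9 genes of naive cells 3 fell (5 adjusted over the list alone), among them Klf2 (−0.99). Some lists share members, such as Cxcr6 (Th1 and non-Tfh effector), Il10 (type 2 and Treg), Ltb4r1 (Th17 and ILC2) and Tcf7 (Tfh and naive). Calls of such lists are not independent. Of 30 acute stimulation genes 7 rose and 4 fell (8 and 7 adjusted over the list alone), with Il2 (1.20), Dusp5 (1.49) and Ccl4 (3.09, uncertain because Ccl3 and Ccl4 are close paralogs) among the rises. Of 25 proliferation genes 2 rose (3 rose and 1 fell adjusted over the list alone), Hmgb2 by 0.36 and Rrm2 by 0.81, the latter in 2 of 3 mice and −0.0056 without mouse 2. The histamine synthesis gene Hdc, from the mast cell and basophil list, rose by 3.60 and the dendritic cell gene Cst3 by 0.81, the former in 2 of 3 mice. The stress gene Atf3 rose by 0.86, in 2 of 3 mice. Of 8 B-cell genes 2 passed, where the antigen presentation gene Cd74 rose by 1.01, reversing to −0.14 at matched depth, and the antibody gene Ighm fell by 0.64.

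At a false discovery rate of 0.05, edgeR called 237 of 7435 genes (161 higher, 76 lower). Camera called the type 2 (adjusted p = 1.2e-48), non-Tfh effector (4.2e-54), Th1 (9.4e-11), Th17 (9.5e-06) and naive (4.6e-05) lists, the last lower. Each of these 5 held with an estimated correlation, at camera adjusted p of 0.019, 0.018, 0.037, 0.037 and 0.037 in this order. Tfh genes were called lower (7.1e-05, adjusted p = 0.16 with an estimated correlation), and Treg genes higher (2.8e-05, adjusted p = 0.16 with an estimated correlation), as were proliferation genes (0.012, adjusted p = 0.33 with an estimated correlation). The proliferating cluster made up 10.3% of the cells of this sort but held 2.78% of its Il13+ cells. At matched depth the Tfh list pointed higher (adjusted p = 0.70) and the proliferation list lower (adjusted p = 0.43), neither called. Acute stimulation genes, not called before (camera adjusted p = 0.072), were called higher at matched depth (1.3e-15). In all comparisons, camera calls at matched depth were not checked with an estimated correlation. With Csf2 at its bound the type 2 median stayed at 1.81. The count was 120 without mouse 1, 150 without mouse 2 and 538 without the proliferating cluster. With reference cells matched for depth (medians of 4696.5, 5348 and 3902 UMIs, deeper than the Il13+ cells of mice 1 and 2) it was 143 of only 3214 genes tested. When 10 UMIs defined an Il13+ cell it was 373 (166 higher, 207 lower), where mouse 3 had only 3 Il13+ cells and gave no Il13+ sum. Il13+ cells were few (26, 31 and 11 per mouse) and deeper, with medians of 4235, 4303 and 3894 UMIs against 3208, 3331 and 3541.

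The Il13+ cells of the Tfh sort were then described by cluster. A non-Tfh effector-like cluster of 59 cells held 29 of the Il13+ cells (14, 12 and 3 per mouse), and 39 (12, 19 and 8) lay in other CD4 clusters. The cluster was named by its effector markers, and its leading genes were Il3, Il13, Ccl1 and Il5. In the other clusters Il13 reached 861 ± 119 CPM against 4292 ± 2042. Among Il13+ cells Il5 was seen only in the effector cluster (630 ± 125 CPM), with 0 of the 39 other cells holding a UMI, which allows a share of up to 7.69%. Il3 stood at 2209 ± 1403 CPM in the effector cluster and 62.3 ± 108 in the others, Csf2 at 232 ± 218 and 2.97 ± 5.14, and Ltb4r1 at 253 and 11.9. Gata3 was 497 ± 91.9 CPM in the effector cluster, 152 ± 64.8 in the other Il13+ cells and 138 ± 18.6 in Il4+ Il13− cells. The other Il13+ cells carried Tfh transcripts near the level of Il4+ Il13− cells, with a wide spread. Cxcr5 was 106 ± 73.1 CPM against 100.3 ± 8.31, where the effector cluster had 26.8 ± 14.8, and Sostdc1, a secreted BMP and Wnt antagonist of Tfh cells, was 348 ± 282 against 201 ± 23.7 and 31.1 ± 27.1. Il4 was highest in them, at 3933 ± 649 CPM against 2687 ± 1487 in the effector cluster and 1676 in Il4+ Il13− cells, and Pdcd1 was 392 ± 112, 344 ± 121 and 218 ± 21.3. Foxp3, the Treg regulator, had a UMI in 0 of 29 and 0 of 39 Il13+ cells (up to 10.3% and 7.69%) but in 14 of the 24 Il13-negative cells of the effector cluster (58.3%). These cell groups were described, not tested.

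**Figure D1:**
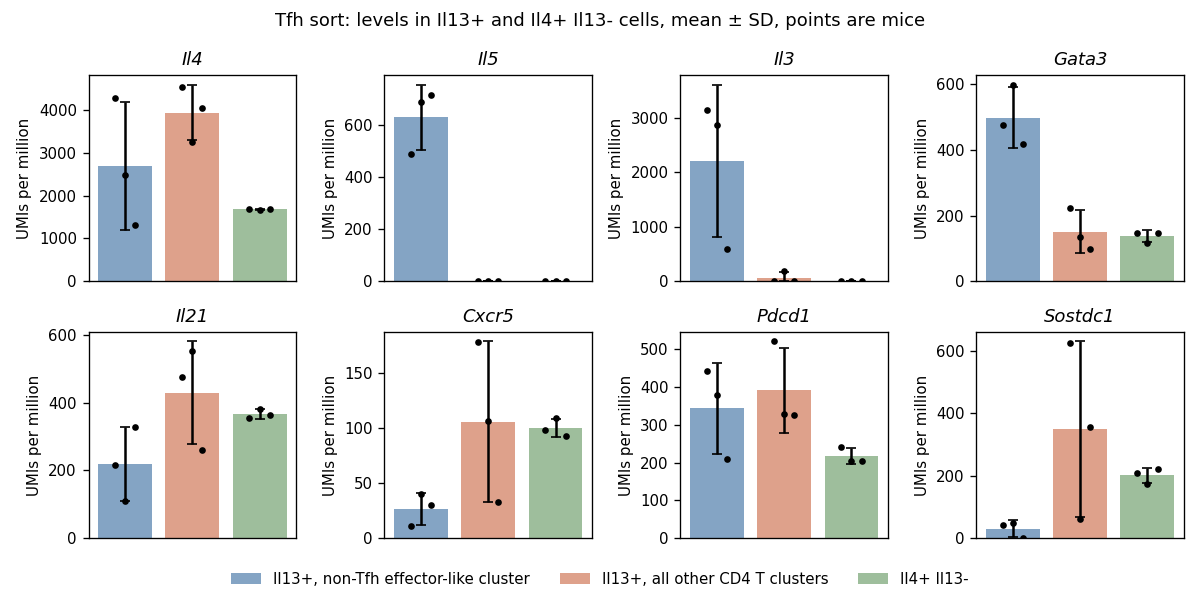
UMIs scaled to CPM for 8 genes in Il13+ cells of the effector-like cluster, in the other Il13+ cells and in Il4+ Il13− cells of the Tfh sort (bars are means, error bars SD, points 3 mice, axes from 0). Il5 (630 CPM) and Il3 (2209 CPM) stand high in the effector-like cluster, where mouse 3 has only 3 Il13+ cells. Cxcr5 is low in that cluster, and in the other Il13+ cells (106 CPM, wide spread) it lies near the level of Il4+ Il13− cells.

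Without that cluster edgeR called 62 genes (30 higher, 32 lower), 40 of them shared with the 237. Mouse 3, with 8 Il13+ cells left, gave no Il13+ sum there. In 20 random removals of as many Il13+ cells per mouse, with the same loss of mouse 3, edgeR called 87 to 245 genes. Of the 13 type 2 genes that had risen, 9 were tested again and 0 stayed called by edgeR. Gata3 went from 1.35 ± 0.156 SE to 0.27 ± 0.290, Areg, an epithelial repair factor gene, from 1.33 ± 0.151 to 0.46 ± 0.160, and Plac8 from 6.24 ± 0.38 to 2.94 ± 1.15. Ccr8 (1.97 ± 0.46 to 1.53 ± 0.716) and Rbpj (1.66 ± 0.288 to 1.06 ± 0.488) lost the call with less change in fold and a larger SE. Of 12 non-Tfh effector genes that had risen, 11 were tested again and 5 stayed called by edgeR. These were Vim (1.37), Anxa2 (1.02), S100a6 (0.99), Lgals1 (0.66) and Crip1 (0.51), where the random removals kept 8 to 12. The effector genes were not held out of the clustering, nor were the type 2 genes Plac8, Igfbp7, Ccr8 and Epas1. Most effector genes also named the cluster, so a larger loss than by random removal was built in. Cxcr6 turned to −0.93, Id2 to −0.53, Il2ra to −0.15 and Hmgb2 to −0.25. The other Il13+ cells were 1.33% of the CD4 cells outside the cluster, beside 0.694% of B-like cells (4 of 576), which should lack Il13, at median depths of 2814 UMIs for CD4 cells and 2138.5 for B-like cells. The 4 B-like cells lay in a cluster of 116 cells with a median of 5280.5 UMIs and 110 ± 101 CPM of Il13, and the other 460 B-like cells had 3.14 ± 3.20 CPM and 0 Il13+ cells (up to 0.652%).

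The next comparison asked what separates IL-4-transcribing cells of the Tfh sort from cells without Il4 and Il13. Ifng and several chemokine genes fell. Of the genes that fell, Gzmk, Ccl5, Xcl1 and Nkg7 were among the leading genes of a Th1-like cluster of 45 cells, and Penk, Il2ra, Tnfrsf9 and Ccr8 of a Treg or Tfr-like cluster of 122 cells. Ifng fell by 1.94 ± 0.13 SE, from 188 to 48.2 CPM (edgeR adjusted p = 5.1e-20, 3 of 3 mice), and the cytotoxic granule gene Nkg7 fell from 63.6 to 3.27 CPM (−4.11). The chemokine genes Ccl5 (−3.60), Xcl1 (−2.85), Ccl4 (−2.31) and Ccl3 (−2.21) fell too, the last pair with paralog reads uncertain, as did the type 1 homing receptor Cxcr3 (−1.33). Gzmk, a granzyme gene, was 37.6 times lower (interval 10.0 to 317). Akr1c18, a progesterone-metabolising enzyme gene, rose the most, from 9.90 to 59.8 CPM (2.60 ± 0.24 SE, edgeR adjusted p = 8.2e-14, 3 of 3 mice).

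Further rises were in the unconventional myosin gene Myo6 (1.59), Lgals7 (1.39), Hist1h1e (1.03, uncertain among histone paralogs), Dusp16 (0.87), the vitamin D receptor gene Vdr (0.87), E2f1 (0.85), Itpa (0.79), Dynlt1f (0.75, uncertain among paralogs) and Gins2 (0.75). Further falls were in the enkephalin gene Penk (−1.91), Mgst2 (−1.50) and the growth factor receptor gene Igf1r (−1.26). Gata3 rose by 0.46 (edgeR adjusted p = 0.0054, 3 of 3 mice). Il21 (0.09), Bcl6 (0.16), Cxcr5 (−0.16) and Pdcd1 (0.04) did not pass, nor did Il5, with 4 counts against 2.

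Of 9 Th1 genes 4 fell (5 adjusted over the list alone) and 0 rose. Of 25 proliferation genes 10 rose (18 adjusted over the list alone), among them Hmgb2 (0.32), Ube2c (0.40), Cenpa (0.40, in 2 of 3 mice) and Birc5 (0.35). Of 9 Treg genes 5 fell, including Il2ra (−1.12), Tnfrsf9 (−1.02), Capg (−0.82) and Ikzf2 (−0.42). Of 30 acute stimulation genes 5 fell (6 adjusted over the list alone), such as Jun (−0.59). Of 16 type 2 genes Gata3 rose and Ccr8 fell (−1.06, in 2 of 3 mice), and of 22 Tfh genes 2 rose, Sostdc1 (0.65) and Tnfsf8 (0.37), and Izumo1r fell (−0.34), with 3 rising and 2 falling adjusted over the list alone. Of 16 non-Tfh effector genes 4 rose, Lgals1 (0.52), Itgb1 (0.54), Anxa2 (0.61) and S100a6 (0.52), with 5 rising and 1 falling adjusted over the list alone. The naive-cell homing gene Ccr7 (−0.89) and Ighm (−0.29) fell, and Ifi27l2a (0.34), an interferon-induced gene, and the lactate dehydrogenase gene Ldha (0.26) rose.

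In this comparison edgeR called 187 genes (78 higher, 109 lower). Camera called Th1 genes lower (2.7e-23), the 1 list here that held with an estimated correlation (adjusted p = 0.017). Proliferation genes were called higher (2.8e-16, adjusted p = 0.073 with an estimated correlation), but lower at matched depth (8.5e-14), where Gins2 turned to −0.0318, Hmgb2 to −0.20, Ube2c to −0.46, Cenpa to −0.16 and Birc5 to −0.52. Without the proliferating cluster these genes stood at −0.0240, −0.0304, −0.65, −0.13 and −1.08. Treg (1.5e-09, adjusted p = 0.084 with an estimated correlation), naive (0.0011, adjusted p = 0.084 with an estimated correlation) and NKT genes (8.6e-04, adjusted p = 0.17 with an estimated correlation) were called lower. Acute stimulation genes were called lower too (1.4e-04, adjusted p = 0.35 with an estimated correlation), and higher at matched depth (0.028). Only at matched depth did camera call Tfh (adjusted p = 3.1e-09, 0.22 before), type 2 (0.011, 0.16 before) and plasma cell genes (0.028, 0.66 before) higher. Non-Tfh effector (0.0011, adjusted p = 0.19 with an estimated correlation) and glycolysis genes (0.0049, adjusted p = 0.19 with an estimated correlation) were called higher. The count of 187 was 55, 88 and 77 without mouse 1, 2 and 3, 25 by DESeq2 and 121 without the mouse as a block. At matched depth it was 73 of 6223 genes tested. It was 82 without the Th1-like and Treg or Tfr-like clusters, 85 without the proliferating cluster, 108 with 1 UMI as positive and 311 with only the 2 states fitted. Without the Th1-like and Treg or Tfr-like clusters Ifng (−1.63), Nkg7 (−2.79), Ccl4 (−0.83) and Cxcr3 (−1.24) still passed, Penk (−0.93), Tnfrsf9 (−0.45), Capg (−0.38), Ikzf2 (−0.16), Il2ra (−0.90) and Ccl3 (−0.43) did not, Ccr8 turned to 0.12, and Gzmk, Ccl5 and Xcl1 were not tested.

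**Figure D2:**
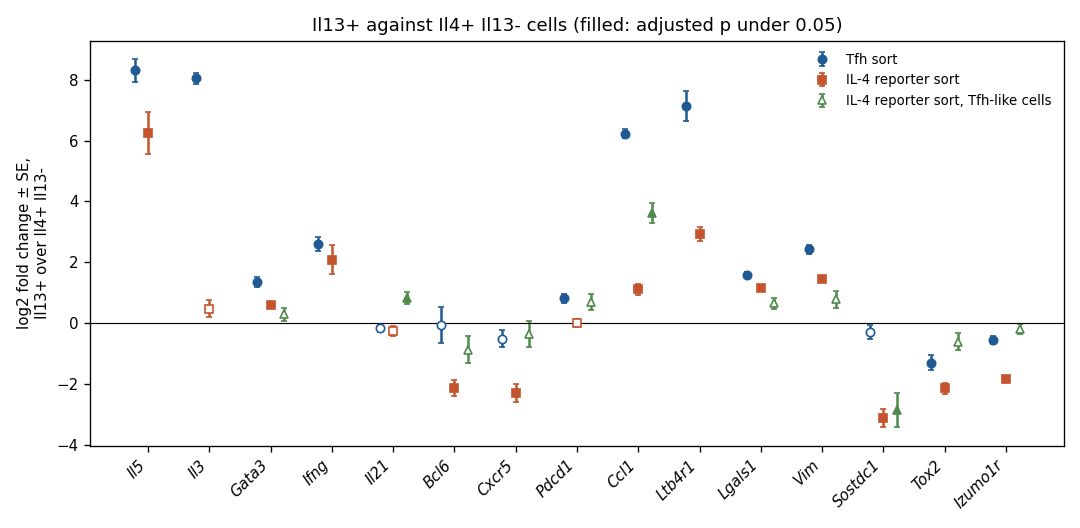
Log2 fold change ± SE of named genes in Il13+ over Il4+ Il13− cells of the Tfh sort, the IL-4 reporter sort and its Tfh-like cells, filled where the edgeR adjusted p is under 0.05. Cxcr5 and Bcl6 lie below 0 and are called in the reporter sort (−2.30 and −2.13), and Il5 in that sort rests on 1 count in the reference state.

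In the IL-4 reporter sort the same question was asked of Il13+ and Il4+ Il13− cells. Of 22 Tfh genes 18 fell, and 10 of 19 type 2 genes rose (adjusted p = 0.14 for the type 2 list with an estimated correlation). The states differed in cell make-up. Of 42, 52 and 84 Il4+ Il13− cells per mouse 15, 22 and 44 were Tfh-like, and of 248, 256 and 158 Il13+ cells 12, 15 and 14. Cxcr5 fell from 23.2 to 5.05 CPM (−2.30, edgeR adjusted p = 8.1e-06, 3 of 3 mice) and Bcl6 from 36.6 to 8.44 CPM (−2.13, edgeR adjusted p = 5.5e-06, 3 of 3 mice). Sostdc1 fell by 3.11. Il5 stood at 54.2 ± 39.8 CPM against 0.356, 104 times higher with an interval of 18.6 to 4120. Pparg, a regulator of pathogenic Th2 cells, rose by 2.78, Ltb4r1 from 27.2 to 209 CPM (2.92), and Gata3 from 239 to 366 CPM (0.61, edgeR adjusted p = 8.8e-05, 3 of 3 mice).

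Other large rises were in Il6, at least 27.2-fold with 0 counts in the reference, the neutrophil chemokine gene Cxcl2 (55.4 times, interval 9.89 to 2190), Hist1h1a (3.01, uncertain among histone paralogs), the MHC class II genes H2-Eb1 (2.94) and H2-Aa (2.90), Coro2a (2.92) and the nuclear receptor gene Rora (2.82). Large falls were in H2-Q2 (−3.56, uncertain among MHC class I paralogs), the cytokine receptor gene Il6st (−2.97), the B-cell coactivator gene Pou2af1 (−2.91), Nsg2 (−2.79), Igf1r (−2.50), Ephx1 (−2.44), Gpm6b (−2.44), Dennd2d (−2.34) and Fam101b (−2.34). Ifng rose by 2.08, Il21 changed by −0.27 and Pdcd1 by 0.01, the last 2 not passing. Without the proliferating cluster Il21 rose by 0.69 (edgeR adjusted p = 6.0e-04).

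Beside these, 0 Tfh genes rose, with Tcf7 (−2.06), Tox2 (−2.15), Izumo1r (−1.85) and Sh2d1a (−1.57) among the falls. Of 19 type 2 genes 10 rose, including Il5, Plac8 (2.29), Pparg and Gata3, and Tnfsf11 fell. All 25 proliferation genes rose, such as Cdk1 (1.38), Ube2c (1.27), Birc5 (0.90) and Hmgb2 (0.75), but without the proliferating cluster Cdk1 stood at −1.29 and Ube2c at −0.11. Of 30 acute stimulation genes 3 rose and 19 fell (20 adjusted over the list alone), such as Cd69 (−0.91), Fosb (−0.98), Rel (−0.96) and Zfp36 (−0.83), which stood at 0.0195 at matched depth. Of 16 non-Tfh effector genes 10 rose and 1 fell (3 fell adjusted over the list alone), including Vim (1.44), Lgals1 (1.15), Crip1 (0.98) and Emp3 (0.88). Of 12 naive genes 2 rose and 7 fell, including Ccr7 (−1.99) and Lef1 (−1.38). Of 14 Th1 genes 6 rose and 2 fell, with rises in Cxcr6 (1.29), Nkg7 (2.56) and Runx3 (0.60), and 4 of 9 Th17 genes rose, including Il17a (2.12). Of 13 Treg genes 2 rose and 5 fell, with Il2ra at 1.27, Ikzf2 at −1.71, Ctla4 at −0.98 and Tnfrsf4 at −0.59.

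Of 16 glycolysis genes 8 rose (11 adjusted over the list alone), including Tpi1 (1.22), Eno1 (1.07), Ldha (0.54) and Gapdh (0.43). Of 10 heat shock genes 7 rose and 1 fell, with Hspd1 (1.32), Hsph1 (1.33), Hsp90aa1 (1.03) and Hspe1 (0.74) rising. Hsp90aa1 stood at −0.0610 without the proliferating cluster and Hspe1 at −0.0222 at matched depth. Of 13 interferon genes 1 rose, Bst2 (0.79), and 6 fell, including Ifi27l2a (−1.36) and Ifi203 (−0.81). Of 10 B-cell genes 3 rose, Cd74 (1.61) and H2-Ab1 (2.48) among them, and Ighm fell (−0.65, 0.10 with a stricter cell filter). Hdc rose by 1.16 (2 of 3 mice) and Cst3 by 0.65. Of 4 ILC2 genes 3 rose (4 adjusted over the list alone), Il7r (0.92) among them, and of 4 NKT genes 2 fell, Slamf1 (−1.54) and Cd160 (−1.53). Low counts bounded several genes: Klrg1 was at least 7.37-fold, Ccl5 at least 5.37-fold and Il22 at least 3.42-fold higher, and the intervals were 6.59 to 1470 for Ccl3 (37.0 times), 1.71 to 394 for Gzma (9.86 times) and 2.09 to 64.5 for Il18rap (7.72 times), where paralogs leave Ccl3 and Gzma uncertain. With such genes at their bound the ILC2 median moved from 4.63 to 1.9, the Th17 median from 1.55 to 0.837 and the Th1 median from 0.808 to 0.364.

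In this sort edgeR called 2676 of 10025 genes (1348 higher, 1328 lower). Camera called Tfh genes lower (5.8e-36) and proliferation genes higher (4.8e-27), and these 2 lists held with an estimated correlation (adjusted p = 0.044 for both). It called 12 more, each lost with an estimated correlation. Type 2 (1.5e-09, adjusted p = 0.14 with an estimated correlation), non-Tfh effector (3.4e-08, adjusted p = 0.19 with an estimated correlation), Th1 (0.0073, adjusted p = 0.21 with an estimated correlation) and Th17 genes (6.2e-04, adjusted p = 0.19 with an estimated correlation) were higher. Glycolysis (1.8e-06, adjusted p = 0.12 with an estimated correlation), heat shock (5.8e-05, adjusted p = 0.16 with an estimated correlation) and ILC2 genes (1.4e-05, adjusted p = 0.12 with an estimated correlation) were also higher. Naive (7.5e-08, adjusted p = 0.12 with an estimated correlation), Treg (0.045, adjusted p = 0.35 with an estimated correlation), interferon (4.7e-04, adjusted p = 0.19 with an estimated correlation) and NKT genes (0.022, adjusted p = 0.15 with an estimated correlation) were lower. Acute stimulation genes were lower (2.1e-08, adjusted p = 0.12 with an estimated correlation) and higher at matched depth (0.0020). The 662 Il13+ cells had median depths of 12606, 13577 and 19253.5 UMIs against 7577.5, 7445 and 8169.5 in the 178 Il4+ Il13− cells. The count was 442 of 7095 genes tested at matched depth. It was 992 without the proliferating cluster, 1220 with 3 UMIs as positive, 1200 with a stricter cell filter, 1655 without mouse 2 and 1413 without mouse 3. Without the cluster led by macrophage genes it was 2736, with H2-Aa (2.76) and H2-Ab1 (2.27) still called.

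Within Tfh-like cells of the IL-4 reporter sort the same states were compared, to ask whether Il13 marks a program there. In the Tfh-like clusters Tfh markers were higher on average by 0.49 to 1.74, with 0 or 1 among the 10 leading genes of each. A Tfh-like cluster of 97 cells, led by Stfa3, Spp1 and Apoe, came mostly from mouse 3 (6.19% of its cells, against 0.818% and 0.0872% in the others). Ccl1 rose from 40.1 to 604 ± 569 CPM (3.62 ± 0.32 SE, edgeR adjusted p = 1.5e-08, 3 of 3 mice). Il21 rose from 280 to 494 CPM (0.81, edgeR adjusted p = 0.047, 3 of 3 mice). The activation genes Nfkb1 (1.02), Batf (0.97) and Tnfrsf4 (0.82), the hypoxia gene Hilpda (1.81), the histone gene H2afz (0.95) and the chaperone gene Hsp90ab1 (0.42) rose too. Sostdc1 (−2.87), Fosb (−0.61) and the nuclear RNA Malat1 (−0.47) fell, though Sostdc1 stood at 0.0881 with 1 UMI as positive. Gata3 (0.29), Bcl6 (−0.87), Cxcr5 (−0.37) and Pdcd1 (0.69) did not pass.

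Of 20 Tfh genes 2 rose and 1 fell (4 and 4 adjusted over the list alone). None of 5 type 2 genes and none of 13 non-Tfh effector genes passed over all genes, though 7 of the latter rose and 1 fell adjusted over the list alone, and 1 of 7 Treg genes rose (2 adjusted over the list alone). Camera called type 2 (0.015, adjusted p = 0.24 with an estimated correlation), Treg (0.015, adjusted p = 0.35 with an estimated correlation) and non-Tfh effector genes (1.2e-04, adjusted p = 0.24 with an estimated correlation) higher. All 3 calls were lost at matched depth (adjusted p = 0.79, 0.79 and 0.33), where camera called proliferation genes lower (0.024). EdgeR called 12 of 2714 genes (8 higher, 4 lower), from 41 Il13+ cells. The count was 5 without mouse 1 and 31 without mouse 3. It was 3 without the mouse as a block, 4 with only the 2 states fitted, 7 with 1 UMI as positive, 29 under the ratio rule for hashtags, 25 at a finer clustering and 36 without a filter on low counts. At matched depth edgeR called 0 genes, with 164 of 1866 at an unadjusted p under 0.05, from mice 2 and 3 only, since mouse 1 had 9 cells left in each state. The share of Tfh-like cells with an Il13 UMI (11.8 ± 1.79%, median depth 6239) was that of B-like cells (11.9 ± 7.06%, median depth 4588). With 2 or more UMIs the shares were 2.48 ± 0.562% and 0.575 ± 0.995%, the latter from 1 cell of 193, so Il13 expression in these cells was not separated from background.

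Tfh-like and Th2-like cells of the IL-4 reporter sort were then compared in genes kept out of the clustering. Il13 was far lower in Tfh-like cells, at 29.1 ± 8.92 against 2014 ± 1108 CPM (−6.00, edgeR adjusted p = 2.2e-12, 3 of 3 mice), where B-like cells had 30.4 ± 12.9. Il4 was lower by less, at 37.9 against 110 CPM (−1.55). Gata3 fell from 541 to 136 CPM (−1.99), and the cytokine genes Il5 (−6.61), Il17a (−6.28), Csf2 (−6.21), Il6 (−6.13), Il3 (−5.90) and Il10 (−4.36) were lower, as were the regulators Prdm1 (−4.44) and Pparg (−4.31). Bcl6 was higher in Tfh-like cells, at 63.2 against 11.2 CPM (2.44), with the inhibitory receptor gene Btla (1.52) and Cd200 (1.11). EdgeR called all 28 genes tested, 4 higher and 24 lower. The remaining calls were Tnf (0.37) and lower levels of Areg (−2.49), Rbpj (−2.19), Nfil3 (−1.10), Ifng (−0.93, in 2 of 3 mice), Irf4 (−0.85), Batf (−0.81), Tnfsf11 (−0.64), Maf (−0.54), Icos (−0.36), Il21 (−0.36), Cd40lg (−0.29), Il2 (−0.26) and Tnfsf8 (−0.21, in 2 of 3 mice). When UMIs of Cxcr5 and Pdcd1 defined the classes, Cd200 turned to −0.24, Tnf to −0.44 and Maf to 0.0362.

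Among Il13+ cells alone the same classes still differed. Tfh-like Il13+ cells had 414 ± 78.6 CPM of Il13 against 2691 ± 1041 in Th2-like ones (−2.64, edgeR adjusted p = 1.9e-10, 3 of 3 mice), and 205 against 580 CPM of Gata3 (−1.48). Both classes were cut on 2 or more Il13 UMIs, which sets a lower limit on Il13, so its values describe the cells and are not a result. Il13 in the Tfh-like cells was also not separated from background. Il21 was higher, at 503 against 357 CPM (0.49, edgeR adjusted p = 0.0049, 3 of 3 mice). Il4 was lower by 0.70 (65.6 against 105 CPM, edgeR adjusted p = 0.033, 3 of 3 mice). Il3 was at least 21.5-fold lower, Ifng and Il17a at least 11.3-fold lower, and Csf2 was 49.2 times lower (interval 8.77 to 1950). Cd200 (1.68), Btla (1.35), Tnfsf8 (0.65), Tnf (0.60) and Il2 (0.80, in 2 of 3 mice) were higher, and Il10 (−2.97), Pparg (−2.57), Prdm1 (−1.99), Rbpj (−1.66) and Areg (−1.56) lower. EdgeR called 18 of 25 genes, 6 higher and 12 lower, Il13 among the latter.

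Il13+ cells made up 1.87 ± 0.508% of the cells of the Tfh sort, and 2.26, 2.64 and 1.64% of the CD4 cells of its 3 mice (median depth 2814) against 0.708 ± 0.346% of B-like cells (median depth 2138.5). In the IL-4 reporter sort they made up 17.5 ± 5.42% of cells, and 18.7 ± 5.45% of CD4 cells (median depth 6744) against 0.575 ± 0.995% of B-like cells (median depth 4588). With every cell thinned to 1500 UMIs the shares were 1.24% and 10.2%. With 1 Il13 UMI as positive they were 4.52% and 26.5%, and a stricter cell filter raised the reporter share to 32.9%. In the Tfh sort the effector-like cluster (47.8 ± 4.68% Il13+) held 40.3% of all Il13+ cells, and the largest CD4 cluster, which has no name by its markers and is led by Srxn1, Sostdc1, Egr4, Tnfsf8, Il4, Cdh23, Ctsl and Cxcr3, held 33.3% (3.59 ± 0.710% Il13+). In the reporter sort a Th2-like cluster held 48.3% of them and a proliferating cluster 40.2%, at 59.5 ± 14.2% and 59.9 ± 9.60% Il13+, with median depths of 8591 and 25120 UMIs. With cells thinned to 1500 UMIs, 40.5 ± 17.5% of the Th2-like and 26.2 ± 11.7% of the proliferating cluster were Il13+. In the Tfh sort the thinned shares were 41.6 ± 11.25% in the effector-like cluster and 1.34 ± 0.378% in the largest CD4 cluster.

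**Figure D3:**
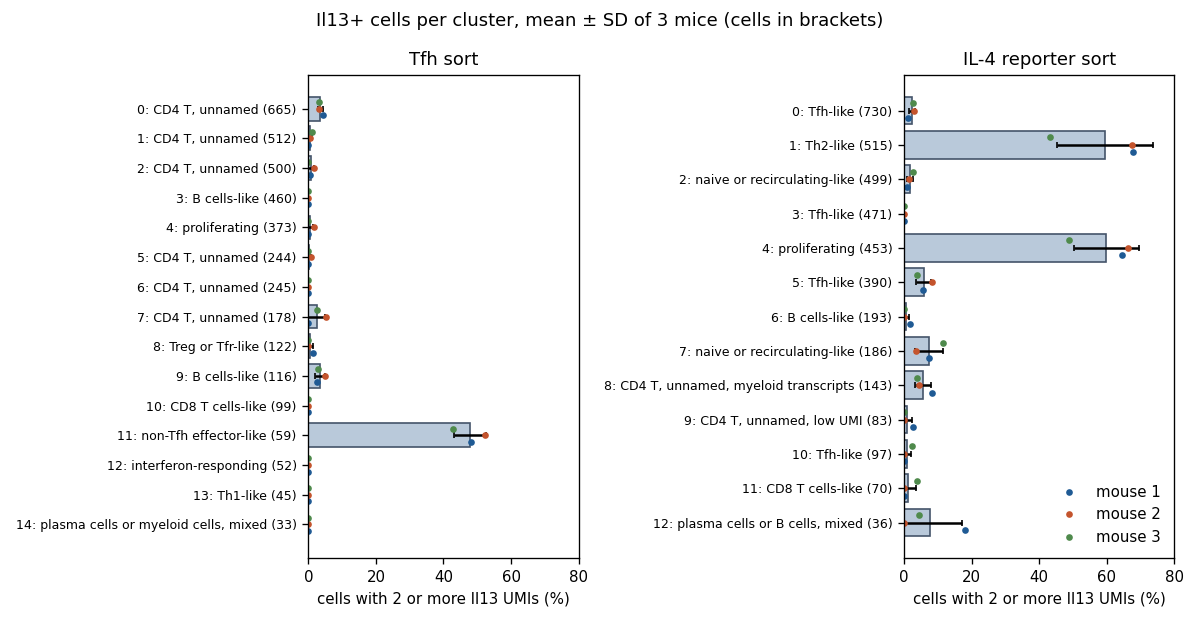
Percent of cells with 2 or more Il13 UMIs in each cluster of the 2 sorts (bars are means, error bars SD, points 3 mice, cell numbers in brackets). The effector-like cluster of the Tfh sort (47.8%) and the Th2-like (59.5%) and proliferating (59.9%) clusters of the reporter sort stand above the others.

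Across the 7415 genes tested in both sorts, Il13+ against Il4+ Il13− cells gave 106 shared higher genes of 160 and 1224 (26.4 if calls were independent) and 66 shared lower genes of 76 and 1196 (12.3 if independent). Called in opposite directions were 9 genes. Fold changes across genes had Pearson r of 0.267 and Spearman rho of 0.257, though genes are not independent replicates. With Tfh-like reporter cells only, 5 of 2707 genes tested in both were shared. Ccl1, H2afz and Hilpda were higher (0.254 genes if independent), and Fosb and Malat1 lower (0.103 if independent). With depth matched in both sorts 3206 genes were tested in both and 70 were shared. Of these, 66 were higher (5.8 if independent) and 4 lower (Clec2i, Dennd2d, H2-Q2 and Rps20, 1.72 if independent). Il5, Ltb4r1, Plac8, Lgals1 and Vim rose in both sorts, and Dennd2d and Tox2 fell in both. Tox2 was not among the shared genes at matched depth, nor was Plac8, which was not tested at matched depth in the Tfh sort.

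**Figure D4:**
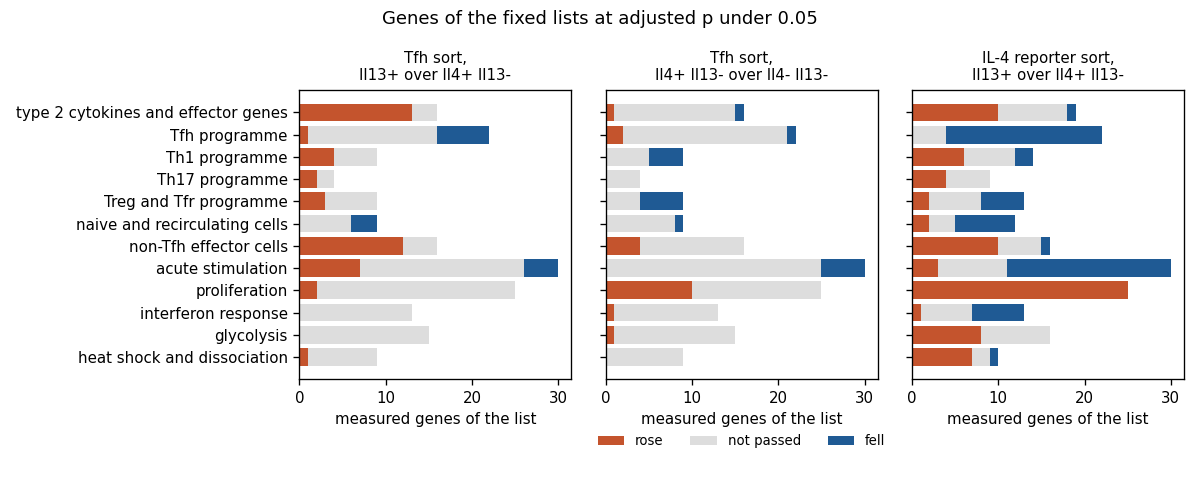
Number of measured genes of each fixed list that rose, fell or did not pass at an edgeR adjusted p under 0.05 in 3 comparisons. Type 2 genes rose in both sorts (13 of 16 and 10 of 19), and 18 of 22 Tfh genes fell in the reporter sort.

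Over the 4 genome-wide comparisons camera called 33 of 59 lists tested, 8 of which held with an estimated correlation. At matched depth, tested with the preset correlation only, 19 of the 33 kept their call and 3 were called the other way. Another 2 (Th17 in the Tfh sort and ILC2 in the reporter sort) could not be tested. Median, mean and test had the same sign in each called list. Of the 17 programs and cell types tested in the reporter sort, lists such as glycolysis (Ldha), interferon (Ifi27l2a) and heat shock (Hspe1) were not called in the Tfh sort for Il13+ against Il4+ Il13− cells, and the difference between sorts was not tested.

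Side by side and untested, CD4 cells of the 2 sorts differed in the levels of several cytokine genes. Il4 stood at 902 ± 24.1 CPM in the Tfh sort and 46.6 ± 3.51 in the reporter sort, with B-like backgrounds of 189 ± 43.4 and 6.55. An Il4 UMI was in 54.8% of CD4 cells of the Tfh sort (14.7% of B-like cells) and 27.6% of those of the reporter sort (2.46% of B-like cells), at the median depths given for the Il13 shares. Il13 was 112 ± 60.0 and 654 ± 313 CPM, Gata3 126 ± 9.53 and 247 ± 22.2, and Il21 354 ± 1.32 and 220 ± 21.8. Il5, at 12.3 ± 3.13 and 22.8 ± 15.6, overlapped between mice of the sorts (10.7, 15.9 and 10.2 against 37.4, 24.7 and 6.35). B-like cells of the Tfh sort had 17.8 ± 28.0 CPM of Il5. The Tfh markers Cxcr5 (109 ± 10.3 and 27.5 ± 4.23) and Pdcd1 (221 ± 10.8 and 114 ± 8.54) were higher in the Tfh sort, and Bcl6 was 16.6 ± 1.37 and 30.3 ± 4.28. Ifng was 111 ± 25.8 and 40.8 ± 1.74, and Foxp3 8.26 ± 3.98 and 1.16 ± 0.397. Even Il13+ cells of the reporter sort had 52.5 ± 9.95 CPM of Il4 where those of the Tfh sort had 3257 ± 1112, so few reporter cells reached 2 Il4 UMIs. The genes lie at 53602982 to 53618669 for Il4 and 53631324 to 53634702 for Il13 on chromosome 11, 44511787 to 44561877 for Cxcr5 on chromosome 9, 23965052 to 23988852 for Bcl6 on chromosome 16 and 9857078 to 9890034 for Gata3 on chromosome 2.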

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

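Among the tests below, those of other kinds of Il13+ cells, of the effector-like cluster (limited to type 2 genes after its result was seen) and of free RNA in Tfh-like reporter cells were written before their results were seen, and those of depth, of the effector genes without that cluster, of the reporter allele, of free RNA in the Tfh sort, of doublets and of other splits were chosen after.

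The comparison of Il13+ with Il4+ Il13− cells was searched for opposite signs only among the genes named for it. Of these, 6 had the same sign in all Tfh-sort mice and the opposite sign in all mice of the reporter sort or its Tfh-like cells. In each of these pairs 1 side did not pass. Over all 7415 genes tested in both sorts, 9 were called in opposite directions. The chaperone gene Hsp90aa1 stood at −0.16 (not passed) in the Tfh sort and 1.03 in the reporter sort, and the mitotic gene Ube2c at −0.55 (not passed) and 1.27. Against Tfh-like reporter cells, Il21 stood at −0.16 (not passed) and 0.81. Cd200 stood at −0.87 and 0.43, Klf2, a quiescence factor gene, at −0.99 and 0.21, and Pcf11 at −1.58 and 0.19, where the reporter values did not pass. These differences were not tested.

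Signals also appeared in cells that the comparisons leave out. Plasma-like cells, by their antibody transcripts, were present in both sorts. In a plasma and myeloid cluster of the Tfh sort (33 cells) 6295 UMIs of Ighe, the IgE heavy chain, and 11609 of Ighg1, the IgG1 heavy chain, were counted, where the other 3670 cells held 201 and 965. In a plasma and B-cell cluster of the reporter sort (36 cells) 3043 and 2918 were counted, where the other 3830 cells held 76 and 148. Among reporter-sort barcodes above the mitochondrial limit, 237 of 2772 had 2 or more Il13 UMIs (8.55%, exact 95% interval 7.54 to 9.65%). The same held for 43 of 554 barcodes without a hashtag (7.76%, 5.67 to 10.3%) and 47 of 165 with several hashtags (28.5%).

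The first weighed pattern is the low Il4 of the reporter sort, where Il13+ cells had 62.0 times less Il4 CPM than those of the Tfh sort. Lower depth does not bring it, since CD4 cells of the reporter sort were 2.4 times deeper by median UMIs. Other kinds of Il13+ cells do not bring the whole of it, since the effector-like cells alone kept a ratio of 25.1 (2687 ± 1487 against 107 ± 8.48 CPM). The other 16 type 2 genes had ratios from 0.558 to 19.7 (median 1.09), so the loss was strongest for Il4. A candidate explanation is the GFP cassette after the Il4 coding sequence in the 4get strain, which may move 3′ tags off the annotated gene, but allele, strain, chemistry and run differ together and cannot be told apart.

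The second is the rise of type 2 and effector genes in Il13+ cells of the Tfh sort. Depth does not bring the whole change, since 9 of the 13 type 2 genes stayed called at matched depth. Only 9 of the 13 could be tested there, so each gene tested kept its call. Free RNA does not bring all Il13+ cells, since at equal depth 1.31 ± 0.615% of CD4 cells (1.43 ± 0.719% in another random thinning) and 0.381 ± 0.33% of B-like cells were Il13+, higher in CD4 cells in 3 of 3 mice. Without the effector-like cluster 0 of 13 stayed called (9 could be tested again), where 20 random removals of as many Il13+ cells kept 6 to 12, so the type 2 rises may come largely from that cluster, though Ccr8 and Rbpj lost the call more by a larger SE than by a smaller fold. The calls of effector genes do not come from it alone, since 5 of 12 (Vim, Anxa2, S100a6, Lgals1 and Crip1) stayed called (11 could be tested again). That fit had no Il13+ sum of mouse 3. The random removals kept 8 to 12, but effector genes were open to the clustering and most of them named the cluster. The type 2 genes Plac8, Igfbp7, Ccr8 and Epas1 were open to the clustering too. A larger loss than by random removal was thus built into leaving out the cluster. Free RNA in the Il13+ cells outside it cannot be told apart from expression, because 39 of 2936 cells were Il13+ against 50.5 expected from the pooled B-like rate, which rests on 79 counts in 9 cells, and 0.901 expected from the share of B-like cells with a UMI. All 4 Il13+ B-like cells lie in 1 cluster of 116 cells, so B-like cells give no common rate.

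The third is the presence of Il13+ cells among Tfh-like reporter cells. Free RNA may bring them, since 41 of 1688 cells were seen where 28.0 were expected from the B-like rate (bound 69.0) and 17.8 from the share of B-like cells with a UMI (bound 52.0), but this rate rests on 29 counts in 193 B-like cells. Doublets with Th2-like cells cannot be told apart, because Il13 stood at 13.3% of its Th2-like level but Csf2 at 2.03% on 1 count and Il3 at 4.66% at the floor.

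Other ways to split the 6 sums of each gene comparison number 10, the real one included, too few for a share under 0.05. In each comparison 1 of the 10 splits, the real one, gave as many genes. The real count was 237 for Il13+ against Il4+ Il13− cells of the Tfh sort, with 17 as the highest other, and 187 with 9 for Il4+ Il13− against Il4− Il13− cells. It was 2676 with 1 for the reporter sort, 12 with 3 for its Tfh-like cells, 28 with 0 for the held-out genes and 18 with 0 for them in Il13+ cells.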

How the results depend on the processing

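Cells with 10 or more Il13 UMIs, leaving out the proliferating, the effector-like, the Th1-like and Treg or Tfr-like clusters or the cluster with macrophage transcripts, cells with a Cxcr5 or Pdcd1 UMI and shares in CD4 cells only were tried after the data were seen. Except where a construction shows it (fewer cells or genes), the cause of a change was not tested.

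For Il13+ against Il4+ Il13− cells of the Tfh sort (237 genes), leaving out a mouse gave 120 to 204, matched depth 143, 10 UMIs 373 (166 higher, 207 lower), no proliferating cluster 538 and no effector-like cluster 62. Without the mouse as a block it gave 218. For Il4+ Il13− against Il4− Il13− cells (187), DESeq2 gave 25, no block 121, only 2 states 311, leaving out a mouse 55 to 88, 1 UMI 108, matched depth 73, no proliferating cluster 85 and no Th1-like and Treg or Tfr-like clusters 82. For the reporter sort (2676), leaving out a mouse gave 1413 to 2615, 3 UMIs 1220, matched depth 442, the stricter filter 1200 and no proliferating cluster 992, while leaving out the cluster with macrophage transcripts gave 2736. For its Tfh-like cells (12), no low-count filter gave 36, no block 3, only 2 states 4, leaving out a mouse 5 to 31, 1 UMI 7, the ratio rule 29, resolution 1.5 gave 25 and matched depth 0 by edgeR, with 164 genes at an unadjusted p under 0.05. The class comparisons stayed within 1.5 times of 28 and 18. Matched depth also left fewer genes to test. They were 3214, 6223, 7095 and 1866 in the 4 genome-wide comparisons in this order, against 7435, 7435, 10025 and 2714.

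The Tfh-sort share of Il13+ cells (1.87%) was 4.52% with 1 UMI, 1.24% thinned and 1.63 to 2.14% without a mouse. The reporter share (17.5%) was 26.5% with 1 UMI, 32.9% with the stricter filter, 10.2% thinned and 15.2 to 20.5% without a mouse. The 172 genes shared by the sorts, of 7415 tested in both, became 5 of 2707 with Tfh-like reporter cells. At matched depth they became 70 of 3206, with 66 higher where 5.8 would be shared if independent. Fry called 21 lists where camera called 33.

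Of 3699 values of 238 named genes under alternatives, 3200 kept direction and side of the threshold, and 442 lost and 7 gained the call. In 22 the sign changed with no call under the main or the other setting, and 28 reversed with a call under either of them. In Il13+ cells of the Tfh sort without the effector-like cluster, Cxcr6 stood at −0.93, Id2 at −0.53, Il2ra at −0.15 and Hmgb2 at −0.25. Rrm2 was −0.0056 to 1.11 on leaving out a mouse and Cd74 −0.14 at matched depth. In Il4+ Il13− cells, at matched depth and without the proliferating cluster, Gins2 stood at −0.0318 and −0.0240, Hmgb2 at −0.20 and −0.0304, Ube2c at −0.46 and −0.65, Cenpa at −0.16 and −0.13 and Birc5 at −0.52 and −1.08. Without the Th1-like and Treg or Tfr-like clusters Ccr8 was 0.12. In the reporter sort without the proliferating cluster, Il21 stood at 0.69, Cdk1 at −1.29, Ube2c at −0.11 and Hsp90aa1 at −0.0610. At matched depth Zfp36 was 0.0195 and Hspe1 −0.0222, and with the stricter filter Ighm was 0.10. In Tfh-like cells Sostdc1 was 0.0881 with 1 UMI. With classes by Cxcr5 and Pdcd1 UMIs, Cd200 was −0.24, Tnf −0.44 and Maf 0.0362.

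Mouse 3 gave no Il13+ sum in the Tfh sort with 3 or 10 UMIs, without the effector-like cluster or with a Cxcr5 or Pdcd1 UMI required, nor did mouse 1 for Tfh-like cells at matched depth, so mice and setting changed together there. Too few cells per mouse kept 3 UMIs, 10 UMIs, the stricter filter and classes by Cxcr5 and Pdcd1 UMIs from running for Il13+ against Il4+ Il13− Tfh-like cells, and those classes for Il13+ cells alone.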

Other observations

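Each value here was chosen after the data were seen. Plasma-like cells in these draining nodes carried IgE and IgG1 heavy chain transcripts, a readout of class switching that the sorts were not made for. In the plasma and myeloid cluster of the Tfh sort 13 cells had 100 or more heavy chain UMIs, of which 6 were led by Ighe, the gene for the IgE heavy chain (chromosome 12, 113269260 to 113273248), and 7 by Ighg1, that of IgG1 (113325240 to 113330523). The Ighe-led cells came from 3 mice. In the plasma and B-cell cluster of the reporter sort 7 such cells were led by Ighe (3), Ighg1 (2), Ighg2b (1) and Ighm (1), and the Ighe-led ones came from 2 mice. Jchain, which joins antibody units, had 5910 UMIs in the plasma and myeloid cluster of the Tfh sort against 724 in all other cells, and 4296 against 270 in the reporter sort. These cells are few and were counted without a test.

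A B-like cluster of 116 cells of the Tfh sort was led by the signalling regulator gene Rgs13 and had a median of 5280.5 UMIs. In it 4 cells had 2 or more Il13 UMIs (3.43%), where a larger B-like cluster of 460 cells with a median of 2000.5 UMIs had 0, which allows up to 0.652%. Doublets of B and T cells were not tested for these 4 cells. In the reporter sort the Tfh-like cluster of 471 cells had 0 Il13+ cells, which allows up to 0.637%.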
